A study of Mus musculus with 8 samples.

How the data were processed

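The deposited table, per the file headers, holds for each of 8 arrays a bead summary signal, which is an intensity on a linear scale without normalization, and a detection p-value for each of 25697 probes. The submitters' processing notes name GenomeStudio, without a version. Per the labels' protocols, total RNA was extracted with QIAzol and amplified and biotinylated with an Ambion TotalPrep kit. A second deposited table holds the authors' processed intensities of the same probes. Set against the signals, it keeps each array's order of probes (Spearman correlation above 0.99 on every array), is on a linear scale, has nearly equal medians (18.04 to 18.16) and goes below 0 (lowest value -24.3), as after background subtraction and quantile normalization, though no header names those steps. The genome build behind the probe annotation is not given in the sources used here, so no coordinates are printed.

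Samples were grouped by the genotype in their labels, VP16 or VP16LXRa, with 4 arrays each and no arrays left out. The replicate numbers run on across the groups and pair nothing. Each label names a tumor, and nothing says that the tumors came from separate mice, so p-values measure the spread between these samples. No file names a slide or scan, so batches could not be examined. No 2 arrays held identical values. The raw median signal was 126 to 146 per array, and 44.6% to 47.7% of probes had a detection p-value under 0.01.

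Signals were background-corrected with normexp from the detection p-values, quantile-normalized and put on the log2 scale after adding an offset of 16 (neqc in limma 3.58.1, R 4.3.3). Probes with a detection p-value under 0.01 on at least 4 arrays were kept, 46.2% of all. Group differences are VP16LXRa minus VP16, fitted with limma's lmFit and eBayes, two-sided, with Benjamini-Hochberg adjustment over the kept probes and a threshold of 0.05. The offset shrinks the folds of dim probes. For gene lists each gene was taken at its brightest kept probe. Lists with at least 5 tested members were tested with camera (preset correlation 0.01), adjusted over 27 lists, with the estimated correlation and the directional fry test beside it. Of these, fry also called the LXR targets alone (adjusted p = 0.00163). List scores are means of members after centring each gene over the 8 arrays. Exact permutation tests of the scores used all 35 splits of the arrays into groups of 4 in both orientations, so that the smallest possible two-sided p is 0.0286. After adjustment over the lists no score passed (smallest adjusted p = 0.771). Only 1 list, the LXR targets, reached the smallest possible p, and 1 list at that p cannot pass over 27 lists. The adjusted outcome therefore says nothing against it.

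The tests, 36 gene lists and the rule for naming genes were fixed before the data were examined. Named were up to 12 genes in each direction with the largest differences among probes past the threshold with non-overlapping groups, filled to 6 per direction by the smallest p. To these were added every tested LXR target with Nr1h3 and Nr1h2, up to 3 members of each other tested list by smallest p, and all sex-linked and blood genes. Genes with clone or locus names were left out of the first part, and some list members are not reported here on their own, though the list tests include them. Rad9, Xpnpep2, LOC100048020, Tesk1, Tpmt, Axin2 and Aqp8, and the X-linked genes and Arl5a in the closing section, were chosen after their values were seen. Gene names are those of the array file; 17213 of 18138 matched a symbol or an unambiguous synonym of the GRCm38.p6 annotation, which was used only for names and for the order of genes. Where the probes of an LXR target, a sex-linked gene or a gene named by its rank disagreed this is said. Other list members are given at their brightest probe only. Lists with fewer than 5 tested members (intestinal lipid absorption, bile acid receptor targets, small intestine markers, distal colon genes, mast cells, enteric neurons, adipocytes, blood, sex-linked genes) were not tested as lists; their mean log2 differences, in that order, were 0.14, -0.21, 0.16, -0.10, 0.65, -0.07, -0.07, 1.17 and -0.95.

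Alternatives were no background correction, cyclic loess, median scaling, the authors' processed values, an offset of 50, 3 other filters, trended robust eBayes (camera with a trend only), array weights, leaving out each array, other thresholds, other list tests and the mean of a gene's probes. For left-out arrays the normalized values and probes were kept. A change of sign was counted as a reversal only where an unadjusted p was under 0.05 before or after it. The scripts were tested on simulated data with the real means and residual spreads of the 11875 probes and independent noise. Of 50 probes changed by each of 1, 2, 3 and 4 log2 units, 24, 41, 46 and 49 were called, with 8 false calls. A list of LXR targets raised by 0.5 was called in 40 of 40 sets. The 200 probes were changed at once, which eases the adjusted threshold, so these rates do not carry over to the real data. There Abcg5, with a log2 difference of 4.10, did not pass over all probes (limma adjusted p = 0.688). With no change, 6.67% of 1080 list tests had p under 0.05, and 2 passed the adjusted threshold. The simulated noise was independent between probes, so this rate does not carry over to lists whose members move together. On the real arrays the estimated correlation was as high as 0.93, for smooth muscle markers. There the splits other than the real one gave a median of 9 lists past the adjusted threshold with camera's preset correlation.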

Results

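Total RNA from 8 colon tumor samples of mice was hybridised to 1-colour Illumina BeadChips carrying 25697 probes. All mice carried the Apc min allele, a truncating mutation of the Wnt pathway inhibitor Apc that gives rise to intestinal tumors, on a mixed C57BL/6J and FVB/N background, and all were 8 months old. In 4 samples the intestinal transgene encoded VP16, a viral transcriptional activation domain, alone (VP16 group, replicates 1 to 4). In the other 4 it encoded VP16 fused to the liver X receptor alpha (VP16LXRa group, replicates 5 to 8), which makes this cholesterol-sensing nuclear receptor active without its ligand. Between 11469 and 12257 probes were detected per array, and 11875 probes for 9110 genes were tested. The number of arrays limits the precision of every difference below.

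The comparison asked how a constitutively active LXRα in the intestine changes gene expression in colon tumors. Total RNA of a sample does not tell tumor cells from surrounding colon tissue, so no difference below can be assigned to either. Abcg5 and Abcg8, which together encode the transporter that exports sterols from enterocytes, differed most among the genes higher in VP16LXRa tumors. Abcg5 had a mean log2 intensity of 10.79 ± 0.73 (SD, n = 4) in VP16LXRa and 6.69 ± 1.39 (SD, n = 4) in VP16 tumors, a 17.2-fold difference (log2 difference 4.10, SE 0.67). It was detected in 4 of 4 VP16LXRa and 3 of 4 VP16 tumors, so that this fold is approximate. Abcg8 stood at 8.16 ± 0.73 against 5.19 ± 0.86 (log2 difference 2.98, SE 0.49) and was detected in 4 of 4 VP16LXRa and only 1 of 4 VP16 tumors, so that its fold is not fixed. Srebf1, the transcription factor that drives fatty acid synthesis, was 1.89-fold higher (log2 difference 0.92, SE 0.24), and Scd1, the desaturase that makes monounsaturated fatty acids, was 2.53-fold higher (log2 difference 1.34, SE 0.39). For each of these 4 genes every VP16LXRa tumor lay above every VP16 tumor. Without background correction the log2 differences of Abcg5, Abcg8 and Srebf1 were smaller, 3.07, 1.505 and 0.35.

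These 4 genes belong to a list of 26 known LXR targets, of which 25 were on the array and 19 were tested. As a group the LXR targets were higher in VP16LXRa tumors (camera adjusted p = 2.93e-06; adjusted p = 0.0318 with an estimated correlation), with 15 of the 19 higher and 4 lower and a mean log2 difference of 0.60. The median log2 difference was smaller, 0.16, and without Abcg5 and Abcg8 the mean was 0.26 (camera adjusted p = 0.00353). Without Abcg5, Abcg8, Srebf1 and Scd1 it was 0.14 and the list no longer passed (camera adjusted p = 0.117), both shortened lists being made after seeing the data. The mean score of the list was between 0.23 and 0.40 in the 4 VP16LXRa tumors and between -0.37 and -0.20 in the 4 VP16 tumors (two-sided exact permutation p = 0.0286, the smallest that 4 against 4 allows). Adjusted over the list alone, 4 members passed limma's test: Abcg5 and Abcg8 (both adjusted p = 0.0022), Srebf1 (0.0286) and Scd1 (0.0377). Adjusted over all 11875 probes none passed, with adjusted p = 0.688 for both Abcg5 and Abcg8.

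**Figure D1:**
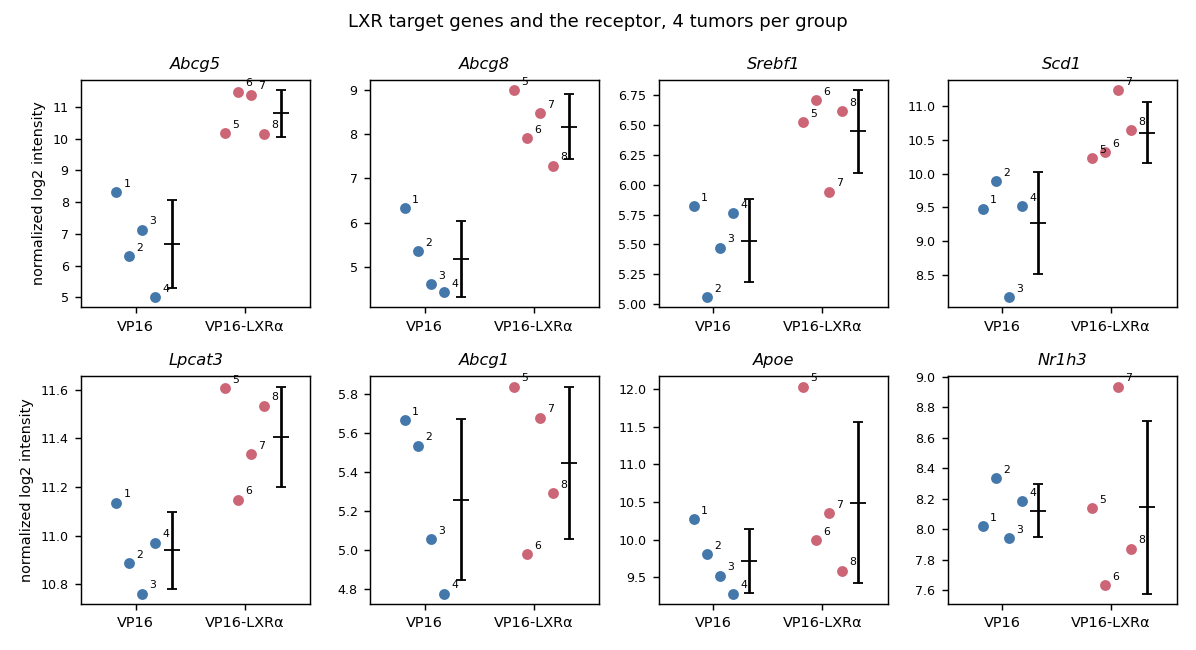
Normalized log2 intensity (y axis, a separate scale per gene) of 7 LXR target genes and of the receptor gene Nr1h3 in each tumor (points, numbered by replicate), with the mean and SD of each group of 4 (black bars). The VP16LXRa points lie above all VP16 points for Abcg5, Abcg8, Srebf1, Scd1 and Lpcat3, and the groups overlap for Abcg1, Apoe and Nr1h3.

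Lpcat3, a phospholipid-remodelling acyltransferase, came next in the list. Both of its probes were higher in every VP16LXRa tumor, by log2 differences of 0.47 (SE 0.16) and 0.60 (SE 0.19), but it did not pass over the list alone (adjusted p = 0.0779). The cholesterol exporter Abcg1 (log2 difference 0.19, SE 0.27), the apolipoprotein Apoe (0.77, SE 0.50), the lipase Lpl (0.39, SE 0.31), Pltp (0.17, SE 0.23), Abca7 (0.15, SE 0.29), Stard4 (0.16, SE 0.25), Scd2 (0.07, SE 0.19), Lpin1 (0.05, SE 0.22) and Arl4c (0.03, SE 0.64) had positive differences that did not pass. Smpdl3a (-0.11, SE 0.60), Mlxipl (-0.07, SE 0.28), Rnf145 (-0.05, SE 0.24) and Mertk (-0.14, SE 0.53) had negative ones that did not pass. Among the 6 targets on the array that too few arrays detected to be tested were Abca1, Mylip, Fasn, Apoc1 and Cd5l.

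The receptor gene itself did not differ detectably. Nr1h3, which encodes LXRα, had a log2 intensity of 8.12 ± 0.17 in VP16 and 8.14 ± 0.57 (SD, n = 4) in VP16LXRa tumors, a log2 difference of 0.02 (95% interval -0.61 to 0.66). Its other probe was detected on no array. Whether either probe matches the transgene is not known, so these values do not check the labels. Nr1h2, which encodes LXRβ, differed by -0.02 (95% interval -0.33 to 0.28).

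Over all probes only 1 passed, that of Eif2s3y, a Y-linked translation initiation factor (limma adjusted p = 0.0458), a call that ended when any array but VP16 replicate 1 was left out. It stood at 8.88 ± 0.73 in VP16 and 5.42 ± 0.09 (SD, n = 4) in VP16LXRa tumors, 11-fold lower in the latter (log2 difference -3.45, SE 0.33). All 4 VP16LXRa tumors lay below all 4 VP16 tumors. The difference was -1.99 without background correction and -2.72 with an offset of 50, neither past the threshold. Eif2s3y was detected in 4 of 4 VP16 and 3 of 4 VP16LXRa tumors. Its VP16LXRa values (5.32 to 5.54) lay near the mean of undetected probes (4.56), so that its fold is not fixed. The other Y-linked genes had smaller differences, none past the threshold. Jarid1d differed by -0.27 (SE 0.34) and was detected in all 8 tumors. Uty, near background, differed by -0.33 (SE 0.21) and was detected in 4 of 4 VP16 and 1 of 4 VP16LXRa tumors. Ddx3y differed by 0.27 (SE 0.20) at its bright probe, while its other 2 probes, and both probes of the female-specific RNA Xist, were detected on no array. Unadjusted p was under 0.05 for 200 of the 11875 probes (1.68%), fewer than the 594 that no effect would give. The 594 is no firm reference here, since the other splits of the arrays gave a median of 350.5 such probes and up to 1477. Groups did not overlap for 152 probes (1.28%), against 2.86% by chance.

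No further gene passed over all probes, and those with the smallest p, clone names aside, are given as values. Higher in VP16LXRa tumors were Cdk5rap1, a tRNA-modifying enzyme (log2 difference 0.90, SE 0.17, with 2 further probes at 0.82 and 0.84), B3galt6, a glycosaminoglycan linker enzyme (1.78, SE 0.35), the calcium-binding annexin Anxa4 (1.16, SE 0.24) and Psmc3ip, a meiotic recombination factor (1.62, SE 0.36). Lower were Rnd3, a small GTPase (-1.54, SE 0.30), the translation termination factor Gspt2 (-1.01, SE 0.20), Raet1b, a ligand of the natural killer receptor NKG2D (-1.67, SE 0.37), Loh12cr1, now named Borcs5 (-0.69, SE 0.15), and the histone gene H2afj (-1.86, SE 0.42). Each of these 9 genes separated the groups completely, and none had an adjusted p under 0.99. B3galt6 was detected in only 2 of 4 VP16 tumors, Raet1b in 2 of 4 and H2afj in 3 of 4 VP16LXRa tumors, so that their folds are not fixed. A further Loh12cr1 probe, detected on 1 array and not tested, went the other way (4.73 in VP16, 5.14 in VP16LXRa). All 9 kept their sign under every alternative, which their choice by smallest p on these same arrays made likely. Their differences shrank in some, at most to 0.75 for B3galt6, -0.70 for Raet1b, -0.33 for Loh12cr1 and -0.93 for H2afj.

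Among the other lipid lists, the fatty acid synthesis genes did not pass as a group (9 of 15 higher, mean log2 difference 0.20, camera adjusted p = 0.0823), though they passed, higher, with array weights (adjusted p = 0.0248) and without VP16 replicate 4 (0.0192) or VP16LXRa replicate 7 (0.0278). Srebf1 and Scd1 led this list, followed by the desaturase Fads1 (0.61, SE 0.44). The cholesterol synthesis and uptake genes showed no shift (9 of 21 higher, mean -0.03, adjusted p = 0.541), with Sqle at -0.46 (SE 0.21) and Dhcr7 at -0.38 (SE 0.22). Fatty acid oxidation genes (6 of 14 higher, mean 0.10, adjusted p = 0.839) included Pdk4, a kinase that restrains glucose oxidation, at 1.23 (SE 0.49), Angptl4 at 0.48 (SE 0.83) and Dci at -0.13 (SE 0.20). Their median, -0.01, had the opposite sign to their mean, and without VP16LXRa replicate 5 they passed, higher (mean 0.33, adjusted p = 0.00524). These calls of the fatty acid synthesis and oxidation lists used camera's preset correlation. With an estimated one, run over all 8 arrays only, neither list passed (camera adjusted p = 0.716 and 0.993). Xenobiotic metabolism genes (2 of 10 higher, mean -0.34, adjusted p = 0.311) were spread widely, with Cyp2c55 at -1.62 (SE 1.91), Gsta4 at 0.68 (SE 0.58) and Nqo1 at -0.28 (SE 0.45).

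No list of growth or death genes passed with the chosen processing. Of the DNA replication and G1/S genes 11 of 20 were higher (adjusted p = 0.975), with Pcna, the replication clamp, at 0.45 (SE 0.18), E2f1 at 0.39 (SE 0.34) and Ccnd2 at -0.43 (SE 0.43). Their median and the direction of the test were positive (median 0.02), while their mean lay just under 0. The mitosis genes Nusap1 (0.38, SE 0.34), Ccna2 (0.29, SE 0.29) and Ube2c (0.31, SE 0.34) belonged to a list with 14 of 16 members higher and an adjusted p of 0.204. Cell cycle inhibitors (2 of 11 higher, adjusted p = 0.273) included Cdkn1a at -0.26 (SE 0.21), Btg2 at -0.19 (SE 0.18) and Btg1 at -0.21 (SE 0.23). Apoptosis genes (8 of 21 higher, adjusted p = 0.411) included Apaf1 at -0.37 (SE 0.24), Pmaip1 at -0.30 (SE 0.21) and Diablo at 0.17 (SE 0.13). Wnt target genes (10 of 12 higher, mean 0.30, adjusted p = 0.278) included Tcf7 at 0.46 (SE 0.34), Wif1 at 1.14 (SE 1.38) and Sp5 at 1.02 (SE 1.38). Genes of the unfolded protein response (10 of 16 higher, adjusted p = 0.896) and immediate early genes (2 of 12 higher, mean -0.24, adjusted p = 0.0701) also stayed short of the threshold, with Chac1 at 0.43 (SE 0.34), Calr at -0.25 (SE 0.22), Pdia6 at 0.28 (SE 0.32), Zfp36 at -0.28 (SE 0.22), Atf3 at -0.26 (SE 0.26) and Junb at -0.38 (SE 0.39). Several of these lists passed when 1 array was left out, and G1/S genes, lower, and the unfolded protein response, higher, also with the macrophage score as a covariate (adjusted p = 0.00551 and 0.00638), an alternative added after seeing the data. Mitosis genes did so, higher, without VP16 replicate 4 (camera adjusted p = 0.000121) or VP16LXRa replicate 7 (0.00449), and over all 8 arrays with array weights (0.0471), and Wnt targets, higher, without VP16 replicate 1 (0.00075) or VP16LXRa replicate 7 (0.0318). Without VP16LXRa replicate 5 the G1/S genes passed, lower (0.0232), and the unfolded protein response, higher (0.0221). Immediate early genes passed, lower, without VP16 replicate 2 (0.03), VP16 replicate 4 (0.0192) or VP16LXRa replicate 8 (0.00884). Cell cycle inhibitors did so, lower, without VP16LXRa replicate 8 (0.0445). All of these calls used camera's preset correlation. With an estimated one, run over all 8 arrays only, no growth or death list passed. It was 0.81 for mitosis genes and 0.77 for Wnt targets (camera adjusted p = 0.948 for both).

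Beside the LXR targets, 3 of the 27 tested lists passed camera with its preset correlation, and none of these 3 did with an estimated one. Macrophage markers were higher in VP16LXRa tumors (12 of 13 members, mean log2 difference 0.42, adjusted p = 0.000389; adjusted p = 0.746 with an estimated correlation), led by Emr1 (0.72, SE 0.34), the complement gene C1qb (0.86, SE 0.42) and the fractalkine receptor Cx3cr1 (0.69, SE 0.35). Interferon response genes were lower (13 of 15 members, mean -0.63, adjusted p = 0.00055; adjusted p = 0.746 with an estimated correlation), led by Ifit3 (-1.12, SE 0.54), Rsad2 (-1.28, SE 0.74) and Oas1a (-0.75, SE 0.43). Enteroendocrine markers were lower (11 of 11 members, mean -0.55, adjusted p = 0.00466; adjusted p = 0.746 with an estimated correlation), led by the substance P precursor Tac1 (-0.85, SE 0.60), Scgn (-0.62, SE 0.47) and Insm1 (-0.60, SE 0.47). No member of the 3 lists passed on its own, and the scores of each list overlapped between groups (exact permutation p = 0.343, 0.429 and 0.457 in that order). Leaving out VP16LXRa replicate 5 brought the macrophage mean to 0.11 and the enteroendocrine mean to -0.01, and leaving out VP16 replicate 4 or VP16LXRa replicate 6 brought the interferon mean to -0.09 or -0.24, each ending the call. The enteroendocrine call also ended without VP16 replicate 3 (mean -0.41, adjusted p = 0.0723).

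The largest differences among the samples did not follow the groups. VP16 replicate 1 and VP16LXRa replicate 5 correlated with each other at r = 0.95 across probes, against 0.833 to 0.924 with the other 6 arrays, and the first principal component, on which they stood apart, held 55.4% of the variance. In these tumors Wnt target genes, inflammatory mediators and neutrophil markers were high and colonocyte and goblet cell markers low. The score of the Wnt targets was 1.26 in VP16 replicate 1 and 1.58 in VP16LXRa replicate 5, and between -0.71 and -0.09 in the other tumors. That of the colonocyte markers was -1.10 and -3.16, against 0.53 to 0.87 in the others. Axin2, a feedback target of Wnt signalling, stood at 11.35 and 11.54 and between 8.51 and 9.15 elsewhere, and the Wnt inhibitor Wif1 at 9.79 and 9.68 and between 4.52 and 7.75 elsewhere. The colonocyte water channel Aqp8 stood at 9.17 and 4.54, against 12.41 to 13.20. The LXR target scores of these tumors, -0.20 and 0.29, lay apart like those of the other tumors of their groups. Without both arrays, an alternative added after seeing the data, the LXR targets still passed (mean log2 difference 0.64, camera adjusted p = 0.000234), with 2 members past the threshold over the list alone in place of 4, and 4 probes passed over all probes: Eif2s3y and Xpnpep2, lower, and Rad9 and LOC100048020, higher in VP16LXRa. Of the 2 tested Rad9 probes the other differed by 0.06 (SE 0.23) over all 8 arrays.

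**Figure D2:**
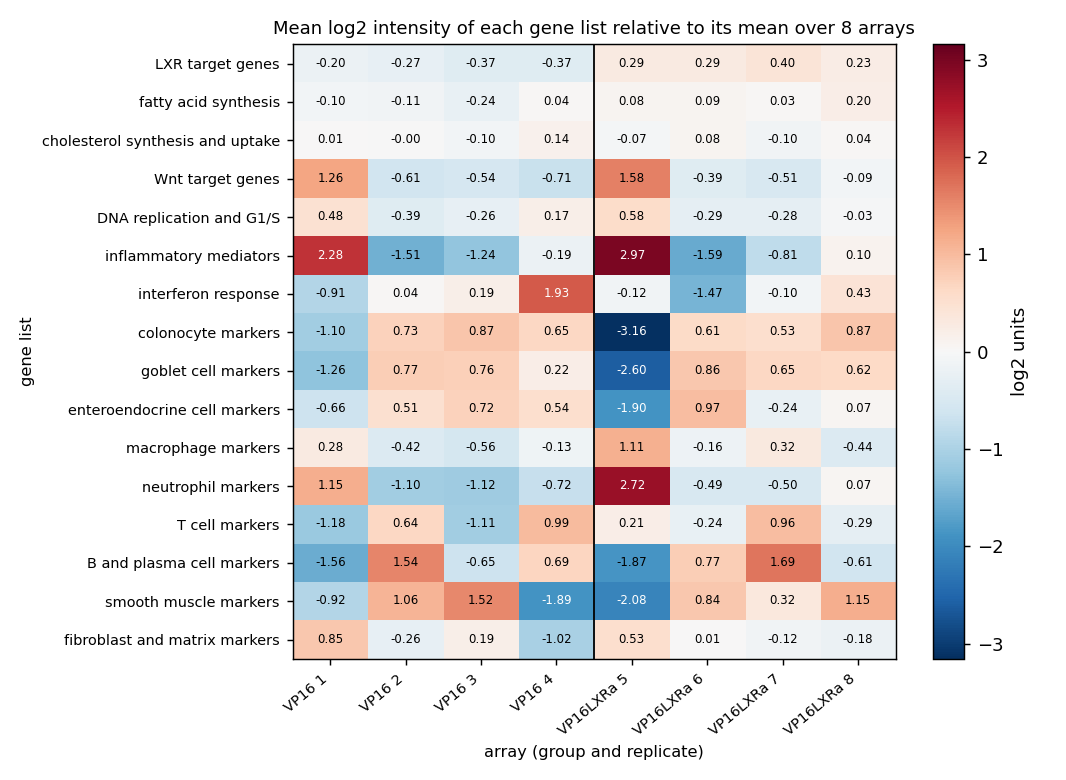
Mean log2 intensity of each gene list relative to its mean over the 8 arrays (colour and printed value, log2 units), for 16 lists (rows) in each array (columns; VP16 left of the line, VP16LXRa right). The LXR target row separates the groups (-0.37 to -0.20 against 0.23 to 0.40), while VP16 1 and VP16LXRa 5 share high Wnt target (1.26 and 1.58) and low colonocyte (-1.10 and -3.16) values.

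**Figure D3:**
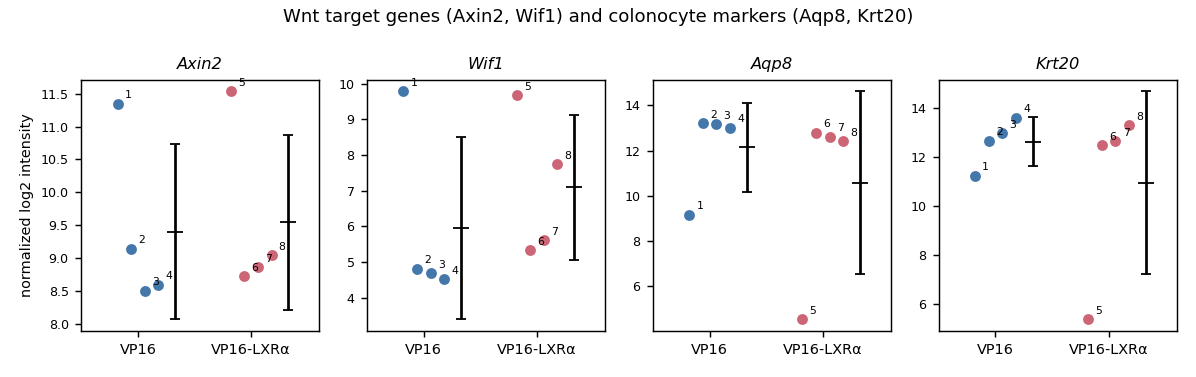
Normalized log2 intensity (y axis, a separate scale per gene) of the Wnt targets Axin2 and Wif1 and the colonocyte markers Aqp8 and Krt20 in each tumor (points, numbered by replicate), with the mean and SD of each group of 4 (black bars). Replicates 1 and 5 lie above all others for Axin2 (11.35 and 11.54) and below them for Aqp8 (9.17 and 4.54).

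None of the lists of other cell types passed with the chosen processing: colonocyte (2 of 15 higher, mean log2 difference -0.57, adjusted p = 0.0701), goblet (2 of 9, adjusted p = 0.39), Paneth (5 of 6, adjusted p = 0.273), tuft (6 of 7, adjusted p = 0.278), fibroblast (12 of 16, adjusted p = 0.411), smooth muscle (9 of 12, adjusted p = 0.839), endothelial (8 of 11, adjusted p = 0.946), neutrophil (5 of 5, mean 0.90, adjusted p = 0.0701), T cell (9 of 9, mean 0.32, adjusted p = 0.204) and B and plasma cell markers (3 of 9, adjusted p = 0.939). Many passed when 1 array was left out, some in opposite directions. Colonocyte markers were lower without VP16 replicate 1 (camera adjusted p = 0.00075) or VP16LXRa replicate 6, 7 or 8 (0.0218, 0.0101 and 0.00154) and higher without VP16LXRa replicate 5 (0.0319). Goblet cell markers were lower without VP16 replicate 1 (0.033) and higher without VP16LXRa replicate 5 (0.028), and smooth muscle markers were higher without VP16 replicate 3 (0.0442) or VP16LXRa replicate 5 (0.00766) and lower without VP16 replicate 4 (0.0441). Neutrophil markers passed, higher, over all 8 arrays with median scaling (mean 0.86, adjusted p = 0.0344) and array weights (0.73, 0.0471), and without VP16 replicate 1 (0.00351), VP16LXRa replicate 6 (0.0273) or 7 (0.00821), or both arrays that stand apart (0.0396). T cell markers were higher without VP16 replicate 2 (0.00953) or 4 (0.000121), fibroblast markers without VP16 replicate 1 (0.00271) or both arrays that stand apart (0.041), and B and plasma cell markers without VP16LXRa replicate 5 (0.0423). With the macrophage score as a covariate smooth muscle (6.98e-06), colonocyte and goblet cell markers (both 0.00558) passed, all higher. All calls in this paragraph used camera's preset correlation. An estimated one was run over all 8 arrays only, and with it none of these lists nor the inflammatory mediators passed. Its camera adjusted p was 0.993 for smooth muscle, 0.892 for colonocyte and 0.948 for goblet cell markers. Single members varied widely within groups. In VP16 and VP16LXRa tumors Krt20, a marker of mature colonocytes, stood at 12.61 ± 1.00 and 10.94 ± 3.73, Lyz1, a lysozyme of Paneth cells, at 7.66 ± 2.20 and 9.54 ± 1.79, and the neutrophil gene Retnlg at 6.03 ± 0.91 and 8.14 ± 1.85 (SD, n = 4). The inflammatory mediators (7 of 11 higher, mean 0.33, adjusted p = 0.839) included Lcn2 at 2.03 (SE 1.91), Mmp10 at 1.57 (SE 2.23) and Cxcl10 at -0.55 (SE 0.71); they passed, higher, without VP16 replicate 1 (0.033) and, lower, without VP16LXRa replicate 5 (0.0319) or with the macrophage score as a covariate (0.00461). The haemoglobin genes Hba-a1 (1.30, SE 0.99) and Hbb-b1 (1.03, SE 0.74), which mark blood, did not pass.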

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

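Splits of the arrays were planned; the tests on the arrays that stand apart, on Eif2s3y in relation to sex and on co-moving list members were chosen after the results were seen. In 33 of 274 groups of 4 values (named genes and list scores) the gap between 1 array and the other 3 exceeded Dixon's 95% limit, where chance gives about 1 in 20 groups (13.7), and that array was VP16 replicate 1 in 10 and VP16LXRa replicate 5 in 11 of them.

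VP16 replicate 1 lay apart in its group for the Wnt targets Wif1 (9.79, others 4.52 to 4.81) and Sp5 (8.92, others 4.45 to 4.94), for Lcn2 (10.98, others 4.89 to 5.42), Mmp10 (12.95, others 4.65 to 5.30) and Cx3cr1 (7.30, others 6.09 to 6.14), all high, and for the goblet cell gene Agr2 (6.78, others 8.43 to 8.74), low. Its list scores lay apart for Wnt targets (1.26), fatty acid oxidation (-0.49), colonocyte markers (-1.10) and enteroendocrine markers (-0.66). VP16LXRa replicate 5 lay apart, low, for Cyp2c55 (4.33, others 12.77 to 13.34), Krt20 (5.36, others 12.48 to 13.29), Klk1 (7.65, others 13.63 to 14.04), Guca2a (10.83, others 15.16 to 15.33), Agr2 (5.74, others 8.42 to 8.81) and Smpdl3a (8.45, others 10.91 to 11.37). It lay high for Anxa4 (10.32, others 9.85 to 9.92) and Cdk5rap1 (8.27, others 7.74 to 7.80). Its list scores lay apart for colonocyte (-3.16) and goblet cell markers (-2.60) and the unfolded protein response (-0.43).

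The arrays VP16 replicate 1 and VP16LXRa replicate 5, 1 from each group, thus share a profile that the genotype does not give, and no biological explanation from the design was tested. Weak signal is argued against, since they detected 11803 and 11890 probes, at or above the 11469 of the lowest array. A smaller share of epithelium alone is argued against only weakly, by non-epithelial lists that moved apart. Neutrophil scores exceeded the mean of the other 3 arrays of their group by 2.13 and 3.04. B and plasma cell scores lay below it (differences of -2.09 and -2.48) by more than the SD of those 3 arrays (1.10 and 1.16). The rule asked for only 1 list in each direction, and an SD of 3 arrays is imprecise. More tumor and less surrounding colon tissue than in the other samples is a candidate explanation that stays open: 11 of 12 tested Wnt targets (91.7%) were higher on both arrays than on every other array, and colonocyte scores were the lowest of their groups on both, values that had been seen before and so describe the pattern without testing it. The criterion set for this explanation also asked for the lowest smooth muscle score of the group. VP16LXRa replicate 5 met it (-2.08). VP16 replicate 1 (-0.92) lay below VP16 replicates 2 (1.06) and 3 (1.52) but above VP16 replicate 4 (-1.89). Another sample low in muscle breaks this criterion whatever replicate 1 holds, so it cannot decide the explanation.

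Eif2s3y was lower in all 4 VP16LXRa tumors, and an effect of the transgene on the gene stays open, untested. Females in the VP16LXRa group would raise genes that escape X inactivation. The mean of Utx and Eif2s3x differed by -0.07 with an upper 95% limit of 0.34, too wide to decide. Ddx3x, an X-linked gene left out of that mean, was higher in VP16LXRa (mean 9.21) than in VP16 (8.998). Its values in VP16LXRa replicates 6 to 8 (9.22 to 9.31) lay above every VP16 value (8.91 to 9.19), and replicate 5 (9.07) did not. Eif2s3x went the other way (9.415 in VP16LXRa, 9.62 in VP16). Both Xist probes were detected on no array. Jarid1d was detected on 4 of 4 VP16LXRa arrays (5.81 to 7.04) and Eif2s3y itself on 3, against 4.56 for undetected probes. The bright Ddx3y probe stood at a mean of 11.30 in VP16LXRa and 11.03 in VP16. What it reads is not known, since the other 2 Ddx3y probes were detected on no array of either group. Uty, detected on 4 VP16 arrays and 1 VP16LXRa array, was lower too, but by only -0.33 (SE 0.21) near background. Its value in VP16LXRa replicate 6 (5.81) lay within the VP16 range (5.46 to 5.94). The Jarid1d values argue against females on these 4 arrays only if their probe reads the Y-linked gene alone, which is not known. Eif2s3y and Uty were lower there, and the labels do not give the sex of the mice, so females stay undecided. A strain variant under the probe, from the C57BL/6J or FVB/N Y chromosome, could lower the signal, but with 1 Eif2s3y probe on the array this cannot be told apart from lower expression. As for the count itself, 3 of the 35 splits of the arrays gave at least the real count of 1 probe, so chance is not excluded for it. The highest other count was 34 where VP16 replicate 1 and VP16LXRa replicate 5 shared a group. It was 4 where they were parted, as in the real split.

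For the LXR target list the splits went against chance as far as 35 splits can: 1 of 35, the real one, gave a p as small (1.09e-07, the smallest of the others 0.00735). The count of lists past the threshold was not distinctive, since 32 of the 35 splits gave at least the real count of 4 and the highest of the others gave 16, which points to structure among the samples. For the macrophage, interferon and enteroendocrine lists, a candidate explanation is that members move together across samples, which the preset correlation understates: with the estimated one the smallest adjusted p of the 3 was 0.746.

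The remaining values far from their group were, in VP16, Cdk5rap1 in replicate 2 (6.77, others 7.07 to 7.08), Dhcr7 in replicate 3 (8.16, others 8.79 to 8.90), Guca2b in replicate 3 (10.60, others 9.89 to 9.92), Btg2 in replicate 4 (6.00, others 6.37 to 6.38), Btg1 in replicate 2 (12.73, others 12.40 to 12.45), Tek in replicate 2 (6.34, others 6.73 to 6.77), Plvap in replicate 4 (8.63, others 9.69 to 9.80) and the tuft cell score in replicate 4 (-0.44, others 0.01 to 0.08). In VP16LXRa they were B3galt6 in replicate 8 (6.55, others 7.22 to 7.34), Dhcr7 in replicate 8 (8.65, others 8.16 to 8.19), Itln1 in replicate 6 (7.11, others 9.83 to 10.13) and Plvap in replicate 7 (9.51, others 9.73 to 9.77).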

How the results depend on the processing

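Leaving out both arrays that stand apart, the covariates and the shortened LXR lists were added after seeing the data; slide as a block was not run because no file names slides. The LXR target list kept its direction under all 26 alternatives and its call under 25, with means from 0.14 to 0.64 (adjusted p from 7.19e-07 to 0.117); without Abcg5, Abcg8, Srebf1 and Scd1 the mean was 0.14 (adjusted p = 0.117). Log2 differences ran from 3.07 to 4.85 for Abcg5 and from 1.505 to 3.36 for Abcg8, lowest without background correction. LXR targets past the threshold over the list alone, 4, became 0 for probes detected on all 8 arrays (which removes Abcg5, Abcg8 and Srebf1), 2 without both arrays or with the macrophage score as covariate, and 2 to 4 without single arrays (2 without VP16 replicate 3, VP16LXRa replicate 6 or 8). Probes past the threshold, 1, became 0 without background correction, with an offset of 50, with no filter, with detection on all 8 arrays (Eif2s3y not tested) and with the macrophage score, 2 with the colonocyte score, 4 without both arrays, and 0 to 2 without single arrays (0 without VP16 replicate 4 or VP16LXRa replicate 6, 7 or 8, 2 without VP16LXRa replicate 5); Eif2s3y kept its sign throughout but lost its call in 11 of 20 alternatives (adjusted p from 0.000293 to 0.347), with log2 differences from -3.81 to -1.99, the smallest fall without background correction. Unadjusted p was under 0.05 for 181, 181, 676, 143 and 449 probes in the alternatives with 0, in that order. Without VP16 replicate 2 the 1 probe past the threshold was that of Tesk1, and without VP16 replicate 3 that of Tpmt, both higher. Without VP16LXRa replicate 5 the 2 were those of Rad9 and LOC100048020, also higher. The receptor gene Nr1h3 stayed uncalled in 21 of 21 alternatives (-0.24 to 0.19). The cause of these changes was not tested unless stated.

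Lists past the threshold, 4, became 1 with an estimated correlation and with fry, 7 with array weights, 9 with the macrophage score and 4 to 10 without single arrays. With an estimated correlation or fry the macrophage (0.42), interferon (-0.63) and enteroendocrine (-0.55) lists kept their means and lost their calls. Without single arrays their means ran from 0.11 to 0.63, -1.04 to -0.0856 and -0.97 to -0.0111; the calls ended without VP16LXRa replicate 5 (macrophage, enteroendocrine), VP16 replicate 3 (enteroendocrine) and VP16 replicate 4 or VP16LXRa replicate 6 (interferon). The enteroendocrine mean was -0.32 without both arrays, -0.22 with the colonocyte score and 0.0918 with the macrophage score, none called. It was also smaller, -0.26, without background correction, though still called with the preset correlation (camera adjusted p = 0.015). Without single arrays the inflammatory mediators ran from -0.60 to 1.17, colonocyte markers from -1.04 to 0.38, goblet cell markers from -0.70 to 0.59, smooth muscle from -0.49 to 0.83, endothelial from -0.17 to 0.21 and B and plasma cell markers from -0.57 to 0.61, with the sign turned, at an unadjusted p under 0.05, without VP16LXRa replicate 5 (inflammatory, colonocyte, goblet, B and plasma) or VP16 replicate 4 (smooth muscle, endothelial). With the colonocyte score the inflammatory mediators were at -0.30 and B and plasma cell markers at 0.39. With the macrophage score Wnt targets were at -0.27 and B and plasma cell markers at 0.50, uncalled; inflammatory mediators (-0.82, adjusted p = 0.00461), colonocyte (0.47, 0.00558) and goblet cell markers (0.69, 0.00558) passed with the sign turned, and smooth muscle markers (1.10, adjusted p = 6.98e-06), fatty acid oxidation (0.39, 0.000192), G1/S genes (-0.24, 0.00551) and the unfolded protein response (0.21, 0.00638) passed; fatty acid oxidation also passed with the colonocyte score (0.25, 0.0107). Immediate early genes were at 0.0363 without both arrays. Of 546 values of the 23 lists that did not pass, 38 passed in the same direction, most without 1 array, and 14 turned. Of 2272 values of the 110 named genes, 2261 kept their side of the threshold and none turned at an unadjusted p under 0.05. Signal over background limits dim genes such as Abcg1, Srebf1 and Abcg8, whose folds the offset shrinks.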

Other observations

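The test on neighbouring genes was chosen after the result was seen. Arl5a, a small GTPase of the Golgi, was lower in VP16LXRa tumors at 3 probes, none past the threshold: its own probe had a log2 difference of -0.80 (SE 0.19) and 2 probes listed as 2810410P22Rik, a synonym of Arl5a in the GRCm38.p6 annotation, had differences of -1.30 (SE 0.18) and -1.40 (SE 0.24). Rnd3, lower as well, lies near it on chromosome 2. Among the genes listed for alleles that differ between mouse strains, 1 of 6 was higher (mean -0.28, camera adjusted p = 0.432). Pla2g2a, a phospholipase that modifies tumor number in Apc min mice, stood at 13.61 ± 1.07 in VP16 and 12.58 ± 1.98 in VP16LXRa tumors (SD, n = 4), H2-Q2 differed by -0.56 (SE 0.78) and Entpd4 by 0.03 (SE 0.17).

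On a mixed background, segments of the C57BL/6J or FVB/N genome that differ between the groups may shift neighbouring genes together. Among the 100 genes with the smallest p there were 27 pairs of neighbours, counted within 20 tested genes on 1 chromosome and leaving out pairs whose symbols share a stem, with the most on chromosome 6 (such as Loh12cr1 and H2afj). Random orders of the 8633 placed genes gave a median of 22 (permutation p = 0.172 over 10000 orders), and 17 of the 35 splits of the arrays gave at least as many. The clustering was thus not beyond chance, which leaves the hypothesis without a positive test but does not exclude single segments.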
